A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

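Each of the 36 arrays compared RNA of a chemostat culture (red, Cy5) with a common reference (green, Cy3) per the labels. The deposited scanner files came from Agilent Feature Extraction 7.5.1, 1 file per array with 10807 spots, of which 544 were controls. Per the file headers the spot and background signals are intensity values, the mean and the median pixel brightness, with no normalization. Per the file headers the log ratio is a log10 ratio of red over green after spatial detrending and LOWESS dye normalization. The deposited value table of the series holds the same ratio as log2 values, within 0.0005 of the log ratio in the scanner files. Other columns hold flags of 0 or 1 per the file headers, for saturation, for a signal well above background and for outlier pixels. Median spot intensity ran from 102 to 399 in red and from 130 to 222 in green, over a median background of 27.5 to 29 in red and 23 to 28 in green, and 84.9% to 93.0% of spots in red and 88.6% to 92.7% in green were well above background. The number of arrays limits the precision.

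Control spots were removed, spots with an outlier flag in either channel (3 to 350 per array) were set to missing, and the rest were background-corrected by normexp with an offset of 50 and normalized by loess within each array in limma 3.58.1 (R 4.3.3). Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package for data tables. Figures were drawn with matplotlib 3.10.9. Spots of a probe were averaged, 4007 probes being spotted in duplicate and 2249 once, and each of the 6256 gene probes had its own gene. The build for which the array was made is not given in the sources used here, so no coordinates are given, and 5756 probes matched locus tags of the R64 assembly by name while 500 did not. Probes were kept when red was well above background on at least 6 arrays and each nutrient had at least 4 values. This dropped 328 dim genes and 31 genes with outlier flags, among them TSC13, ATP15, PGK1, HIS4, LEU2 and PHO89, and left 5897 genes with 0.103% of values missing.

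Samples were grouped by limiting nutrient and dilution rate, from the labels. In limma, a common slope in rate was fitted with a level per nutrient (29 residual degrees of freedom), and a slope per nutrient in a second model (24 residual degrees of freedom), each array entering both. The second model also gave the F test of slope differences, each nutrient's level against the mean of the other 5 at the mean rate of 0.186 per h, and the mean of leucine and uracil against that of the other 4. Slopes are log2 changes over 0.25 per h. Moderated p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and levels also needed a log2 difference of at least 1 to be counted. The 39 gene lists, written from general knowledge before the data were examined, were tested by limma on the mean of the measured members, and their slopes also by camera, with a preset correlation of 0.01 and with an estimated one. By camera with an estimated correlation 0 lists rose and 0 fell after adjustment, against 3 and 3 at an unadjusted p under 0.05. With the preset correlation 9 rose and 10 fell. The rate of each array was predicted from genes fitted on the other 5 nutrients, and permutation p-values of the 6 correlations are exact. Tested on simulated data, the slope test recovered 95% of genes with a slope of 0.5 and called 7 of 5697 unchanged genes, and the level test recovered 100% of genes with a level of 1.5 and called 0 of 5697 unchanged genes at adjusted p under 0.05 in limma. The simulated noise was independent between arrays, with no slope differences between nutrients and no day or slide effects. These shares therefore do not give the error rates in the real arrays.

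Genes were named by a rule set before the data were examined, among 4987 genes with a standard name and red well above background on at least 3 of 6 arrays of every nutrient. It took the 12 largest rising and falling slopes with 1 sign in all 6 nutrients, the 10 smallest p of the F test, the 6 highest and 4 lowest levels per nutrient. It also took the 6 largest differences each way for the auxotrophs and up to 4 members of a list with the largest moderated t. LEU2 and URA3 were named for the strains. OLI1 met the rule but is given no value because it was saturated in red on all 36 arrays. Named genes were saturated in red on some arrays in the case of TEF2, ADH1, PDC1, TPI1, ENO2, ASP3-1, HPF1, ALD4, GPM1, HXT7, DAL5 and VTC1. Genes with a near-identical copy or an overlapping gene are said to be so. Some genes that met the rule are not reported here.

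Extraction days (5) and slides (19, of which 17 held 2 arrays and 15 mixed nutrients) were read per the file headers. Alternatives set before the data were examined were median centring without loess, the Feature Extraction log ratio, an offset of 16, no filter or a stricter filter on dim probes, nominal rates, the log2 of the rate, and a trended robust eBayes. Others set then were slide or day as a random block, day as a fixed term, leaving out each array, nutrient or rate, leaving out both auxotrophs, rate as a factor, a log2 minimum of 1 on slopes, camera, the median of list members, and 50 genes for the prediction. Alternatives chosen after seeing the data were the red channel alone, leaving out the phosphate arrays, leaving them out with day as a fixed term, and keeping spots with an outlier flag.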

Results

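Cultures of budding yeast (Saccharomyces cerevisiae) were held in chemostats, vessels in which the rate of medium inflow sets the growth rate and 1 nutrient of the medium limits it. Messenger RNA was compared on 36 two-colour microarrays, 1 for each combination of 6 limiting nutrients with 6 dilution rates between 0.05 and 0.338 per h, so each condition has a single array and the arrays of a nutrient differ in rate. Glucose, nitrogen, phosphate, sulfate, leucine and uracil limitation had 6 arrays each. The culture was read in the red channel and a common reference, a glucose-limited culture at 0.25 per h per the labels, in the green channel. The nitrogen arrays are labelled nitrate in the sample names and ammonia in the series text, so the limiting compound is called nitrogen here. The leucine arrays came from strain DBY9497 and the uracil arrays from DBY9492, whereas the other 24 arrays and the reference came from DBY10085. Between 84.9% and 93.0% of gene spots per array were well above background in red, and the median red spot intensity ran from 102 to 399. The number of arrays limits the precision of every value below. Of 630 pairs of arrays, 11 had a Pearson r across genes under -0.3, down to -0.57 for glucose at 0.2 per h with phosphate at 0.3 per h, and all 11 included a phosphate array.

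Which transcripts follow growth rate whatever the limiting nutrient was the first question of the design. Ribosomal protein genes rose and stress response genes fell as dilution rate increased. UTR2, a cell wall transglycosylase, rose by 2.43 ± 0.16 (log2 change over 0.25 per h, fitted slope ± SE, n = 36 arrays), and IMD4, an enzyme of guanine nucleotide synthesis, by 2.01 ± 0.14. HSP26, a small heat shock protein, fell by 4.12 ± 0.38, and HXT5, a hexose transporter, fell by 4.02 ± 0.29. In all, 1724 of 5897 genes rose and 2104 fell at an adjusted p under 0.05. The slope had 1 sign in all 6 nutrients for 1151 of the rising and 1305 of the falling genes, and it reached 1 on the log2 scale for 99 rising and 238 falling genes. The largest rises among genes with the same sign in all 6 nutrients also included the ribosomal stalk proteins RPP2A (1.97), RPP1B (1.81) and RPP1A (1.63), the ribosomal proteins RPS28A (1.79), RPL24A (1.71), RPL20A (1.68) and RPL31A (1.64), and the small nucleolar RNA-binding proteins NOP1 (1.70) and SNU13 (1.63). The largest falls also included TMA10 (-3.53), the cell wall protein HPF1 (-3.30), RRT1 (-3.20), GPG1 (-2.93), CSS1 (-2.66), the stress proteins HSP12 (-2.53) and HSP42 (-2.40), DCS2 (-2.49) and NQM1 (-2.47). The mitochondrially encoded OLI1 also qualified, but its red signal was saturated on all 36 arrays and no fold is given. Adjusted p-values of the genes named in this paragraph lay between 2.5e-16 and 5.5e-08. Most ribosomal protein genes have a near-identical copy, as have IMD4 and IMD3, so probes may read both, and IMD4 and RPL7A hold the small nucleolar RNA genes SNR54 and SNR39. With extraction day as a block, 1649 genes rose and 2015 fell, and with the slide as a block 1710 and 2094. Of the 3828 genes called, 3682 had the same sign within the 8 arrays of day 1, 3649 within the 14 arrays of day 2 and 3078 within the 6 arrays of day 3, arrays that are also part of the fit over all days. By limma within a day, 1585, 1656 and 0 of all genes were called, against 2376, 2472 and 1169 at an unadjusted p under 0.05. Day 4 held 2 arrays and day 5 the phosphate arrays alone, and slides held at most 2 arrays, so none of these gave a value of its own.

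Lists of genes chosen before the data were examined moved with rate as groups, 12 of 39 upward and 16 downward in a limma test on list means. By camera with an estimated correlation 0 rose and 0 fell, against 3 and 3 at an unadjusted p under 0.05. The 135 measured cytosolic ribosomal protein genes rose by 0.76 ± 0.11 on average, and 109 of them rose, 3 fell and 23 did not pass the test, with 109 and 3 when adjusted over the list alone. RPL7A (1.63) and RPL18B (0.72) were among the clearest. Median centring in place of loess gave larger slopes for this list (1.67), translation factors (0.80), transfer RNA synthetases (0.79), purine synthesis (1.03), glycolysis (1.77) and the pentose phosphate pathway (0.97). Ribosome biogenesis genes, which assemble ribosomes in the nucleolus, rose by 0.47 ± 0.04, with 87 of 104 rising and 2 falling (88 and 2 adjusted over the list alone), among them GAR1 (1.21), UTP15 (0.87), RCL1 (0.83) and UTP4 (0.72). RNA polymerase I and III subunits rose by 0.50 ± 0.04, and 15 of 19 rose (15 adjusted over the list alone), including RPA49 (1.08), RPA135 (0.89), RPA12 (0.83) and RPC31 (0.59). Mitochondrial ribosomal proteins rose by 0.45 ± 0.06, and 54 of 68 rose and 1 fell (54 and 1 adjusted over the list alone), with RSM26 (1.06), MRPL20 (1.04), MRPL35 (0.80) and MRPL13 (0.80) in front. Against camera with an estimated correlation these calls were lost: adjusted p = 0.37 with an estimated correlation for both ribosomal protein lists and adjusted p = 0.17 with an estimated correlation for ribosome biogenesis and for the polymerases.

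Purine synthesis genes rose by 0.55 ± 0.06, with 15 of 18 rising and 1 falling (15 and 1 adjusted over the list alone), among them IMD3 (1.15), ADE6 (0.68) and PRS3 (0.62). Transfer RNA synthetases rose by 0.41 ± 0.07 (12 of 18, and 12 adjusted over the list alone), including WRS1 (1.23), MES1 (0.72), FRS2 (0.70) and SES1 (0.61). Pyrimidine genes rose by 0.27 ± 0.05 (10 of 15 up and 3 down, and as counted over the list alone 10 and 3), with FUR1 at 1.52 and URA7 at 1.02 against URA10 at -0.93. Translation factors rose by 0.24 ± 0.04 (21 of 35 up and 4 down, with 21 and 4 adjusted over the list alone), with TIF5 at 0.90, GCD1 at 0.58 and GCD7 at 0.43. TEF2, saturated in red on 2 to 5 arrays of every nutrient and so approximate, an elongation factor gene with a near-identical copy in TEF1, had -0.98, a sign that turned to 0.98 with median centring in place of loess and to 0.27 in the red channel alone. The G1/S list of DNA replication genes rose by 0.19 ± 0.04 (21 of 37 up and 4 down, and 21 and 4 adjusted over the list alone), with POL30 at 0.91, TOS4 at 0.76, DPB2 at 0.37 and CLB6 at 0.25. The adjusted p with an estimated correlation was adjusted p = 0.25 for purines, 0.49 for the synthetases, 0.40 for pyrimidines, 0.37 for translation factors and 0.49 for G1/S. Rises also passed for glycolysis (0.39 ± 0.17, 6 of 14 up and 1 down, 4 and 0 adjusted over the list alone), led by TDH2 (1.57) and its copy TDH3 (1.51), ENO2 (1.06) and HXK2 (0.78). By nutrient the glycolysis slope was -0.32 ± 0.32 under nitrogen and -0.75 ± 0.34 under phosphate, against 0.44 to 1.11 under the others. The pentose phosphate pathway (0.33 ± 0.08, 3 of 7, and 3 adjusted over the list alone) followed RKI1 (1.11), SOL3 (0.59) and RPE1 (0.45), while GND1 had 0.15 and did not pass. The mating type a list (0.46 ± 0.17, 4 of 6, and 4 adjusted over the list alone) followed the pheromone receptor STE2 (1.09), BAR1 (0.89), MFA2 (0.64) and AGA2 (0.17). These 3 had adjusted p = 0.76, 0.49 and 0.74 with an estimated correlation, and the glycolysis and mating type calls ended with extraction day as a fixed term (0.39 and 0.30). The mating type a slope was 0.12 without the arrays at 0.05 per h and did not pass.

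All 42 members of the induced environmental stress response fell (42 adjusted over the list alone), by 1.44 ± 0.11 on average. These genes protect cells from heat, oxidants and starvation, and HSP104 (-2.36 ± 0.17), HSP78 (-1.84 ± 0.13), GCY1 (-1.47 ± 0.08) and ECM4 (-0.94 ± 0.07) were the clearest. The list mean is -1.44, and its test had adjusted p = 2.3e-13, with adjusted p = 0.22 with an estimated correlation. Genes of trehalose and glycogen, the storage carbohydrates, had a mean slope of -0.72 ± 0.08 (1 of 21 up and 18 down, and 1 and 18 adjusted over the list alone), with NTH1 at -1.16, ATH1 at -0.92 and NTH2 at -0.69 against PGM1 at 0.72. Chaperones had -0.66 ± 0.11 (2 of 22 up and 15 down, and 2 and 15 adjusted over the list alone), including SSE2 (-1.58) and HSP82 (-1.42). Gluconeogenesis and glyoxylate genes had -1.26 ± 0.20 (14 of 16 down, and 14 adjusted over the list alone), with IDP2 (-2.23), SFC1 (-2.21), the lactate carrier JEN1 (-2.16) and YAT2 (-1.37). The tricarboxylic acid cycle had -0.75 ± 0.09 (13 of 16 down, and 13 adjusted over the list alone), with SDH4 (-1.67), SDH1 (-1.23), LSC2 (-1.01) and KGD1 (-0.92). Autophagy and vacuolar protease genes had -0.52 ± 0.04 (21 of 30 down, and 21 adjusted over the list alone), with ATG8 (-1.14), ATG11 (-0.74), ATG3 (-0.74) and ATG9 (-0.68). Peroxisome genes had -0.49 ± 0.06 (26 of 36 down, and 26 adjusted over the list alone), with POT1 (-1.90), SPS19 (-1.63), POX1 (-1.39) and PEX5 (-0.53). With median centring the chaperone (-0.20) and tricarboxylic acid cycle (-0.20) calls ended. In this order from trehalose to peroxisomes these had adjusted p = 0.37, 0.59, 0.49, 0.37, 0.17 and 0.30 with an estimated correlation.

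Smaller falls passed for 9 more lists. The phosphate regulon had -0.39 ± 0.06 (12 of 16 down, and 12 adjusted over the list alone), with GDE1 (-0.86), PHO81 (-0.74), PHM6 (-0.48) and VTC3 (-0.41). Oxidative stress defence had -0.38 ± 0.04 (4 of 25 up and 13 down, and 4 and 13 adjusted over the list alone), with PRX1 (-1.56), TRX3 (-1.56), TRX2 (-1.17) and TRR2 (-0.90). The hexose transporters had -0.39 ± 0.08 (4 of 15 up and 6 down, and 4 and 6 adjusted over the list alone), with the near-identical HXT7 (-1.84) and HXT6 (-1.67) and the sensor SNF3 (-0.67), and their median member had -0.04. Nitrogen catabolite repressed genes had -0.33 ± 0.09 (2 of 23 up and 12 down, and 2 and 12 adjusted over the list alone), with ASP3-1 (-1.41), which has identical copies, PUT4 (-1.24), DUR3 (-1.06) and UGA1 (-0.66). The M/G1 list had -0.20 ± 0.08 (4 of 21 up and 9 down, and 4 and 9 adjusted over the list alone), with PIR3 (-1.03) and ASH1 (-0.65) against PCL9 (0.43) and CDC6 (0.26). Mating type alpha genes had -0.14 ± 0.05 (2 of 3 down, and 2 adjusted over the list alone), with STE3 (-0.32) and with SAG1 at 0.03, which did not pass. Phosphate carried most of the alpha fall, with a slope of -0.60 ± 0.11 against -0.15 to 0.02 under the other nutrients. The respiratory chain had -0.39 ± 0.10 (14 of 29 down, and 14 adjusted over the list alone), with QCR6 (-1.64), COX9 (-0.90), COX5A (-0.88) and NDE1 (-0.86), and with median centring the list turned to 0.17, as did COX5A and NDE1 in sign. The proteasome had -0.22 ± 0.04 (3 of 31 up and 18 down, and 3 and 18 adjusted over the list alone), with RPT1 (-0.72), RPN1 (-0.65), PRE6 (-0.48) and RPT5 (-0.37), and with median centring the list turned to 0.09, as did PRE6 in sign. Fatty acid and phospholipid synthesis had -0.30 ± 0.07 (4 of 17 up and 8 down, and 4 and 8 adjusted over the list alone), with ACC1 (-1.24) and FAS1 (-0.97) against ELO3 (1.36) and ELO2 (0.80), and with median centring the list turned to 0.25. Of the 3 lists that turned with median centring, 1 passed there as a rise and the calls of the others ended. Median centring also ended the calls of oxidative stress (-0.10), hexose transporters (-0.13), nitrogen catabolite repressed genes (-0.16) and M/G1 (-0.0014). Day as a fixed term ended those of nitrogen catabolite repressed (-0.23), M/G1 (-0.20) and mating type alpha (-0.13) genes. In the order given, the 9 lists had adjusted p = 0.44, 0.49, 0.76, 0.76, 0.80, 0.76, 0.71, 0.49 and 0.76 with an estimated correlation.

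The other 11 lists did not pass. Amino acid synthesis other than branched-chain had 0.15 ± 0.11, the branched-chain list -0.15 ± 0.12, sulfate assimilation 0.10 ± 0.10, the vacuolar ATPase 0.09 ± 0.05, ergosterol synthesis 0.05 ± 0.04 and the zinc regulon 0.09 ± 0.07. Histones had 0.16 ± 0.10, the G2/M list 0.05 ± 0.04, haploid-specific genes 0.09 ± 0.05, meiosis and sporulation -0.06 ± 0.03 and the iron regulon -0.44 ± 0.21. With median centring 6 of them passed, the vacuolar ATPase (0.70), sulfate assimilation (0.54), other amino acids (0.66), ergosterol (0.49), histones (0.90) and meiosis (-0.16). Members went both ways in most lists. For amino acids SER2 (1.03), THR1 (0.99) and LYS9 (0.73) rose, and in the branched-chain list LEU9 (0.73) rose and BAP2 (-1.02), ILV2 (-0.96) and LEU3 (-0.32) fell. In the sulfate list SAM1 (1.04) and MET3 (1.04) rose and MET30 (-1.11) and MET28 (-0.82) fell. VMA7 (0.85), VMA3 (0.68) and VMA5 (0.47) rose and VMA4 (-0.51) fell. ERG24 (0.67), ERG26 (0.60) and ERG12 (0.56) rose and ERG27 (-0.36) fell. ZRC1 (0.98) and ADH4 (0.37) rose and ZAP1 (-0.26) fell. HTB2 (1.10) and HHF2 (0.50) rose, HTB1 had -0.56 and HTA1 -0.12, histone genes with close copies whose signs turned to 0.42 and 0.91 with median centring. CLB4 (0.27) and SWI5 (0.30) rose and DBF2 (-0.68) and MYO1 (-0.47) fell, HO (0.88) and STE5 (0.21) rose and RME1 (-0.54) and AXL1 (-0.28) fell, and SPS4 (0.44) rose and NDT80 (-0.40), SPR28 (-0.36) and ZIP1 (-0.17) fell. Of the iron genes 12 of 20 fell, including HMX1 (-0.91), FRE3 (-0.91), ISU1 (-0.70) and SMF3 (-0.66). The iron list slope was -1.75 ± 0.39 under uracil and -0.89 ± 0.39 under leucine, against -0.39 to 0.69 under the other nutrients. The 2 slowest uracil arrays were extracted on day 3 and the other 4 on day 2, so day may share in the uracil slope. Within days 1, 2 and 3 the stress response had slopes of -0.89 ± 0.20, -1.17 ± 0.19 and -1.94 ± 0.43, cytosolic ribosomal proteins 0.44 ± 0.09, 0.22 ± 0.11 and 2.73 ± 0.49, and ribosome biogenesis 0.46 ± 0.07, 0.33 ± 0.08 and 0.87 ± 0.33 (list slope ± SE). The ribosomal protein slope did not pass within day 2, the largest (adjusted p = 0.11), nor within day 3 (adjusted p = 0.10), where the stress response did not pass either (adjusted p = 0.10). With extraction day or slide as a block 12 lists rose and 16 fell.

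**Figure D1:**
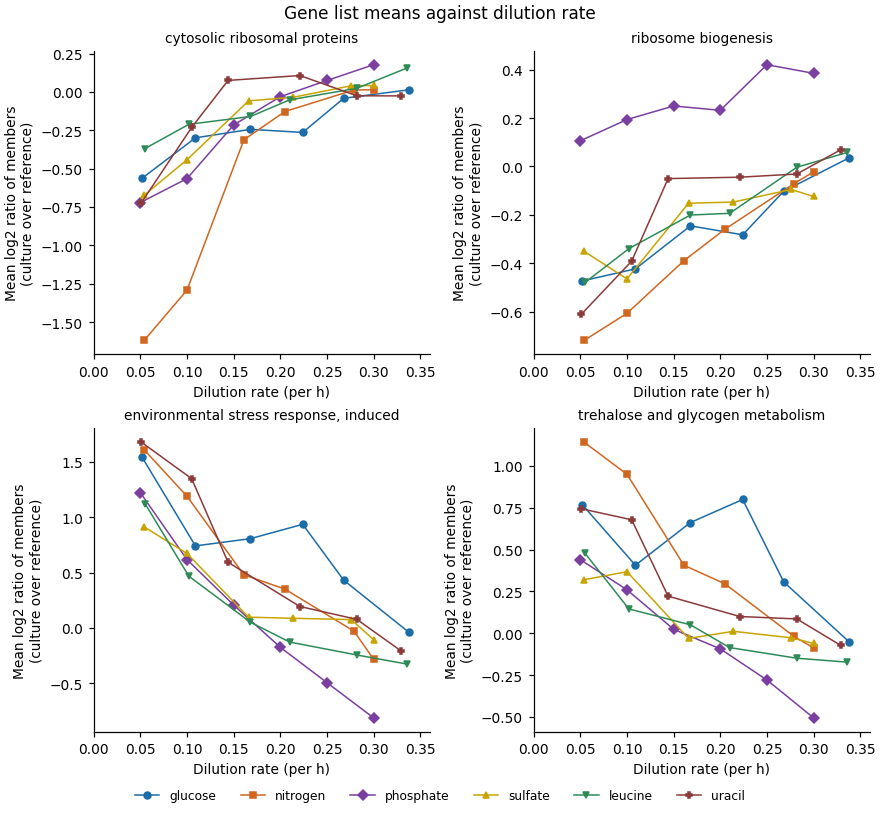
Mean log2 ratio of culture over reference (vertical axis) of 4 gene lists against dilution rate in per h, with 1 point per array and lines joining the 6 arrays of a nutrient. The stress response fell by 1.44 on average over 0.25 per h and cytosolic ribosomal proteins rose by 0.76, with the steepest ribosomal protein slope (1.71) under nitrogen limitation.

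How far growth rate accounts for expression was asked next. Of the variance over all genes and arrays, 59.4% lay between nutrients, 18.6% followed rate within nutrients, 9.0% lay in slopes that differed between nutrients and 13.0% was residual. The share between nutrients also holds the different green channel of the phosphate arrays, described below. The slopes of nutrient pairs correlated across genes with a mean Pearson r of 0.63 (0.53 to 0.75 over 15 pairs), where genes are not independent replicates. Genes fitted on 30 arrays of 5 nutrients predicted the rate of the arrays of the nutrient left out with a mean absolute error of 0.0539 ± 0.0373 per h (SD, n = 36). The error was 0.0532 for glucose, 0.0434 for nitrogen, 0.0263 for sulfate, 0.0410 for leucine, 0.0401 for uracil and 0.119 for phosphate, whose 6 arrays were all predicted too high, by 0.119 per h on average. The prediction uses the ratio, and the green channel of the phosphate arrays, the reference, differed from that of the others. In green the stress response was higher there by 1.06 and ribosome biogenesis lower, at -0.47, so the phosphate offset need not lie in the cultures. Within a nutrient the predicted and actual rates had the same order, with Spearman rho 1 for all 6 (exact permutation p = 0.00278 and adjusted p = 0.00278, two-sided, n = 6 each, 6 relations). Pearson r was 0.969 for glucose, 0.994 for nitrogen, 0.997 for phosphate, 0.951 for sulfate, 0.956 for leucine and 0.900 for uracil, with exact permutation p between 0.00139 and 0.00417 and an adjusted p of 0.00417 for each. Without the 2 arrays farthest from the median rate, r was 0.883, 0.992, 0.999, 0.882, 0.987 and 0.864 in the same order. No day held more than 4 arrays of a nutrient except day 5, which held all 6 phosphate arrays, so r within a day stands for phosphate alone.

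**Figure D2:**
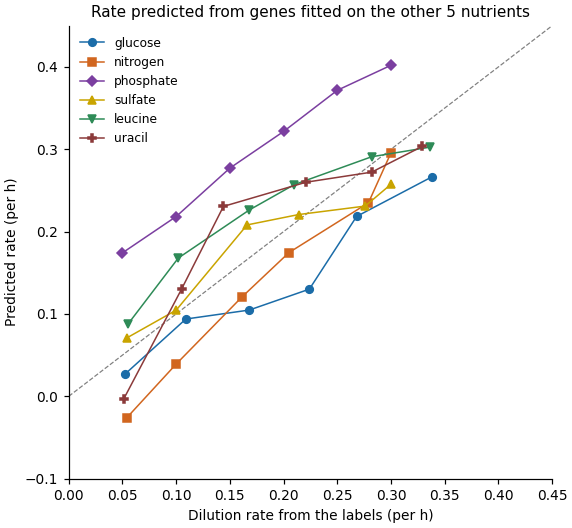
Rate predicted for each of the 36 arrays from genes fitted on the other 5 nutrients (per h, vertical axis) against the rate in the labels (per h, horizontal axis), with lines joining the arrays of a nutrient and the dashed line marking equal values. The order of the rates is kept in all 6 nutrients, and the phosphate arrays, whose green channel differs, lie above the line by 0.119 per h on average.

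Whether the response to growth rate depends on the limiting nutrient was tested by the interaction of rate and nutrient. Several of the genes with the smallest p fell most steeply under glucose limitation. The peroxisomal fatty acid transporter PXA1 had a slope of -2.44 under glucose and between -0.14 and 0.40 under the other nutrients (F = 44.2). FAT3 had -2.54 under glucose and 0.14 to 1.12 elsewhere (F = 38.3), and the acetyl-CoA synthetase ACS1 had -3.68 against -0.67 to 0.03 (F = 32.0). The citrate synthase CIT3 had -2.96 against -0.98 to 0.07 (F = 31) and DCI1 -1.5 against -0.08 to 0.13 (F = 26.1). LEU1, an enzyme of leucine synthesis, had -2.38 under leucine limitation and 0.61 to 1.27 elsewhere (F = 29.2), and the oxaloacetate carrier OAC1 -1.69 against 0.68 to 1.67 (F = 30.7). ZPS1, a zinc-responsive gene, had its lowest slope under phosphate (-1.61, F = 50.1), where SOL3 of the pentose phosphate pathway had its highest (1.87, F = 35.4). MTM1 had slopes of 0.65 to 0.84 under nitrogen, phosphate and sulfate and -0.57 to -0.04 under the others (F = 28.4). In all, 1850 genes differed in slope, with adjusted p up to 7.4e-07 among these 10. The count was 996 with median centring, 1183 without the phosphate arrays, 2877 without the nitrogen array at 0.3 per h and 3258 with the log2 of the rate.

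Some nutrient lists had their steepest fall under their own limitation and others did not, in an F test of slope differences on list means. The sulfate list had a slope of -0.87 ± 0.11 under sulfate and 0.94 ± 0.11 under phosphate (F = 29.5, adjusted p = 1.7e-08), and the peroxisome list had -1.03 ± 0.07 under glucose (F = 19.4). The branched-chain list had -1.13 ± 0.17 under leucine (F = 11.8), nitrogen catabolite repressed genes -1.18 ± 0.15 under nitrogen (F = 7.92) and the phosphate regulon -0.92 ± 0.10 under phosphate (F = 7.88). The phosphate regulon also had slopes of -0.43 to -0.19 under the other 5 nutrients. Hexose transporters had 0.04 under glucose and -0.69 to -0.70 under nitrogen, leucine and uracil (F = 5.77), a difference that ended with the median of list members (F = 0.62). Pyrimidine genes had 0.40 under uracil with no difference called (F = 0.55). Cytosolic ribosomal proteins rose most under nitrogen (1.71 ± 0.19, against 0.43 ± 0.18 to 0.94 ± 0.20 elsewhere, F = 6.65). Slopes differed for 27 of the 39 lists, for 20 with day as a fixed term, for 13 without the phosphate arrays and for 12 with median centring, where the ribosomal protein difference no longer passed (F = 2.07). The phosphate regulon's difference ended with median centring (F = 3.05), with the Feature Extraction log ratio (F = 2.78) and without the phosphate arrays (F = 2.35). The 27 lists also include, by falling F, haploid-specific genes, other amino acids, mating type a, zinc, hexose transporters, oxidative stress, gluconeogenesis and glycolysis. By nutrient, slopes passed for 1772 genes under glucose limitation (820 up and 952 down), 3136 under nitrogen (1479 and 1657), 1857 under phosphate (836 and 1021), 1532 under sulfate (709 and 823), 1677 under leucine (743 and 934) and 2429 under uracil (1046 and 1383). Without the nutrient's own array at 0.05 per h these counts were 896, 1874, 916, 279, 401 and 604, and without the array at 0.3 per h glucose had 1095 and phosphate 1054. With extraction day as a random block the counts were 1759, 3038, 1905, 1503, 1739 and 2277, and with day as a fixed term 1380, 2007, 1977, 410, 1849 and 1462.

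Which genes are set apart by 1 limiting nutrient at the same growth rate was asked by contrasting each nutrient with the mean of the other 5 at the mean rate of 0.186 per h (n = 6 arrays against 30). A gene that is high under 1 nutrient is therefore lower in the contrasts of the other 5. Under glucose limitation, genes that use carbon sources other than glucose were higher. The alcohol dehydrogenase ADH2, a close copy of ADH1, was higher by 5.22 ± 0.25 (log2 ± SE), JEN1 by 4.56 ± 0.18 and the glyoxylate enzyme ICL1 by 4.39 ± 0.30. The mitochondrial succinate carrier SFC1 was higher by 4.04 ± 0.28, the aldehyde dehydrogenase ALD4 by 3.85 ± 0.17 (approximate, since 2 of the 6 arrays were saturated) and the peroxisomal catalase CTA1 by 3.29 ± 0.13, each on 6 of 6 arrays. All 16 gluconeogenesis genes were higher (16 adjusted over the list alone), by 2.88 ± 0.16 on average, including ACS1 (2.68) and the carnitine carrier CRC1 (2.27), and all 16 genes of the tricarboxylic acid cycle (16 adjusted over the list alone), by 1.26 ± 0.07, including SDH1 (2.03), FUM1 (1.75), CIT3 (1.73) and SDH2 (1.63). The gluconeogenesis level depended on rate. Its mean log2 ratio was 2.87 to 3.41 on the glucose arrays up to 0.224 per h, 0.84 at 0.268 per h and 0.20 at 0.338 per h. The glucose transporters HXT1 (-4.07 ± 0.19), HXT3 (-4.03 ± 0.16) and HXT4 (-3.60 ± 0.18) and the ester synthase EEB1 (-2.48 ± 0.28) were lower, while HXT7, near-identical to HXT6, was higher by 3.02. The hexose list therefore had a mean of -0.04 that did not pass, against 0.10 for its median member, which passed. All 14 glycolysis genes were lower (14 adjusted over the list alone), by -1.01 ± 0.13 on average, including GPM1 (-1.74), PDC1 (-1.40), TPI1 (-1.03) and PFK1 (-0.86), of which the first 3 had saturated spots and are approximate, and so were all 6 mating type a genes (6 adjusted over the list alone), -1.02 ± 0.12, including MFA1 (-1.75), STE2 (-1.27), STE6 (-0.84) and BAR1 (-0.83). In all, 125 genes were higher and 45 lower by at least 1. The green channel carried a median share of 0.13 of these contrasts, and without the phosphate arrays 121 genes were set apart and the gluconeogenesis mean was 2.27. The phosphate arrays are also in the mean for glycolysis and mating type a genes. Within days 1, 2 and 3, which have none, gluconeogenesis was at 2.12, 2.10 and 2.63, mating type a at -0.56, -0.61 and -0.91 and glycolysis at -0.74, -0.60 and -0.46, of which glycolysis did not pass within days 1 and 3 (adjusted p = 0.12 and 0.56) nor mating type a within day 3 (adjusted p = 0.095). In the fit over all arrays with day as a random block the count was 168.

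Under nitrogen limitation, permeases and catabolic enzymes for poor nitrogen sources were higher. The allantoate permease DAL5 was higher by 6.86 ± 0.11, the ammonium permease MEP2 by 4.92 ± 0.16, the general amino acid permease GAP1 by 4.77 ± 0.14, the vacuolar carboxypeptidase CPS1 by 4.06 ± 0.11, the proline permease PUT4 by 3.81 ± 0.16 and the allantoin permease DAL4 by 3.78 ± 0.10, each on 6 of 6 arrays. DAL5 was saturated in red on 4 of the 6, so its fitted level and SE are approximate. Nitrogen catabolite repressed genes were higher by 2.47 ± 0.06 on average, with 19 of 23 higher, 1 lower and 3 not called (19 and 1 adjusted over the list alone), including DAL7 (3.34) and DAL2 (3.08). The branched-chain amino acid permeases BAP2 (-2.30 ± 0.12) and BAP3 (-2.29 ± 0.16), which resemble each other, the siderophore transporter ARN1 (-2.18 ± 0.32) and the zinc transporter ZRT1 (-2.13 ± 0.19) were lower. Iron regulon genes were lower by -0.95 ± 0.17 on average, cytosolic ribosomal proteins by -0.36 ± 0.08, zinc genes by -0.60 ± 0.05, and autophagy genes were higher by 0.39 ± 0.03. In all, 65 genes were higher and 43 lower by at least 1. The nitrogen list was at 2.11 within day 2 and 2.80 within day 3. Within day 2 the iron (-0.86) and zinc (-0.55) lists passed, while cytosolic ribosomal proteins (0.01, adjusted p = 0.95) and autophagy (0.22, adjusted p = 0.058) did not, and within day 3 none of these 4 passed. In the fit over all arrays with day as a random block 108 genes were set apart.

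Under phosphate limitation, genes that take up, release and store phosphate were higher. The acid phosphatases PHO11 (6.55 ± 0.07) and PHO12 (5.89 ± 0.07), near-identical copies, the glycerophosphoinositol permease GIT1 (6.19 ± 0.08, on 4 arrays), PHM6 (5.87 ± 0.11) and the polyphosphate synthesis genes VTC3 (4.49 ± 0.05) and VTC1 (4.03 ± 0.08, saturated on 4 arrays and so approximate) led. All 16 measured members of the phosphate regulon were higher (16 adjusted over the list alone), by 4.17 ± 0.04 in the ratio, 4.86 ± 0.04 in the red channel and 0.42 ± 0.01 in the green. The lowest ratios belonged to ADH2 (-5.83 ± 0.25), ICL1 (-5.51 ± 0.31), the malate synthase MLS1 (-5.10 ± 0.29) and SFC1 (-5.07 ± 0.28), where the green channel, the reference, was higher by 5.28, 5.80, 3.97 and 4.87 and the red channel differed by -0.70, 0.04, -1.06 and -0.14. In all, 155 genes were higher and 265 lower by at least 1 in the ratio, 160 genes were set apart in the red channel alone, and 94 of the 420 were called the same way in both, 51 higher and 43 lower. In the green channel alone 311 genes were set apart on the phosphate arrays and at most 4 on those of any other nutrient. Ranked green intensities of phosphate arrays correlated with those of other arrays at Spearman 0.927 to 0.936 across genes, against 0.993 to 0.999 among the other arrays and 0.996 to 0.999 among the phosphate arrays.

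Other lists differed on the phosphate arrays in 1 channel or in both. All 16 gluconeogenesis genes were lower in the ratio (16 adjusted over the list alone), with -3.53 ± 0.16 in the ratio, -0.38 ± 0.18 in red and 3.14 ± 0.03 in green, including PCK1 (-4.07, with 0.00 in the red channel alone), CRC1 (-2.63) and ACS1 (-2.40). In the red channel alone 7 of them were lower and 9 were not called. All 14 glycolysis genes were higher (14 adjusted over the list alone), with 1.80 ± 0.13 in the ratio, 0.53 ± 0.11 in red and -1.09 ± 0.02 in green, including ADH1 (2.63), PDC1 (2.45), TPI1 (1.89) and PFK1 (1.61). The first 3 are approximate, since each was saturated in red on 3 or 4 leucine, 3 to 5 uracil, 2 or 3 nitrogen and 1 or 2 phosphate arrays. The stress response had -0.47 ± 0.09 in the ratio, 0.67 ± 0.10 in red and 1.06 ± 0.01 in green, and ribosome biogenesis 0.52 ± 0.04, 0.08 ± 0.04 and -0.47 ± 0.01. The mating type a genes were higher in ratio (1.52 ± 0.12, 6 of 6, and 6 adjusted over the list alone) and in red (1.39 ± 0.12), including MFA1 (2.47), STE2 (1.92), STE6 (1.56) and AGA2 (0.66). Sulfate assimilation genes were lower in ratio (-1.0 ± 0.04, 25 of 28, and 25 adjusted over the list alone) and in red (-1.14 ± 0.05). Histones had 0.85 ± 0.10 in the ratio and 0.45 ± 0.09 in red. All phosphate arrays were extracted on day 5 and no other array was, so day and nutrient cannot be told apart for them and no value within a day can be had. With day or slide as a random block 416 and 421 genes were set apart.

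**Figure D3:**
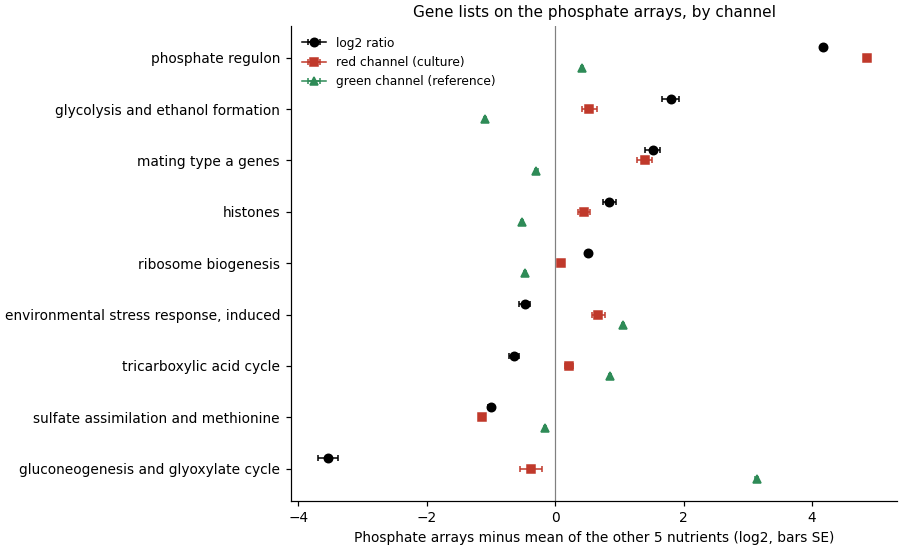
Mean of the members of 9 gene lists on the phosphate arrays minus the mean of the other 5 nutrients (log2, horizontal axis, bars SE), in the ratio, in the red channel (culture) and in the green channel (reference). The phosphate regulon stands apart in red (4.86), whereas the gluconeogenesis list differs by 3.14 in green and by -0.38 in red.

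Under sulfate limitation, genes that bring in and assimilate sulfur were higher. The sulfonate dioxygenase JLP1 was higher by 5.08 ± 0.11, the cysteine transporter YCT1 by 4.44 ± 0.12, the sulfonate permease SOA1 by 4.15 ± 0.11, the sulfatase BDS1 by 4.05 ± 0.08, the pyruvate decarboxylase PDC6 by 4.01 ± 0.16 and the amino acid permease AGP3 by 3.99 ± 0.10, each on 6 of 6 arrays. The sulfate assimilation and methionine list was higher by 1.83 ± 0.04, with 25 of 28 members higher and 2 lower (25 and 2 adjusted over the list alone), including MET14 (2.54) and MET32 (2.27). SER3 (-2.02 ± 0.21), an enzyme of serine synthesis whose gene overlaps the non-coding SRG1, ADH1 (-1.83 ± 0.16, approximate because of saturated spots on the other arrays), the hexokinase HXK1 (-1.83 ± 0.16) and PHO11 (-1.73 ± 0.07) were lower. PHO11 was at -0.43 without the phosphate arrays. Glycolysis (-0.80 ± 0.13), nitrogen catabolite repressed (-0.65 ± 0.06) and iron regulon (-0.56 ± 0.17) genes had lower list means, each against a mean that holds a nutrient where the list was high, phosphate (1.80), nitrogen (2.47) and leucine (1.46). Within day 1, which has no phosphate or nitrogen arrays, glycolysis (-0.23, adjusted p = 0.58) and the nitrogen list (-0.08, adjusted p = 0.54) did not pass. In all, 69 genes were higher and 44 lower by at least 1. The sulfate list was at 1.53 within day 1 and 1.54 within day 2, and with day as a random block 113 genes were set apart.

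Under leucine limitation, permeases for branched-chain amino acids, leucine synthesis and iron uptake genes were higher. BAP3 was higher by 3.82 ± 0.16, FIT3, a cell wall protein of siderophore uptake, by 3.58 ± 0.53, LEU1 by 3.32 ± 0.11 (5 arrays), BAP2 by 3.23 ± 0.12, the drug and cation exporter QDR2 by 2.98 ± 0.09 and the amino acid permease AGP1 by 2.96 ± 0.11. The branched-chain list was higher by 1.55 ± 0.07, with 12 of 14 members higher and none lower (12 and 0 adjusted over the list alone), including OAC1 (2.43). Of the 20 measured iron regulon genes 18 were higher and 0 lower (18 and 0 adjusted over the list alone), by 1.46 ± 0.17 on average, including SIT1 (2.75), FRE1 (2.56), ENB1 (1.98) and FRE6 (1.09). Synthesis genes of other amino acids were higher by 0.46 ± 0.08 (26 of 36, and 26 adjusted over the list alone). They were also higher under glucose limitation, by 0.42 ± 0.08, with 27 of 36 higher and 3 lower. MEP2 (-2.14 ± 0.16), PUT4 (-2.0 ± 0.16), EEB1 (-1.88 ± 0.28) and HPF1 (-1.70 ± 0.29) were lower, where the nitrogen arrays, on which MEP2 and PUT4 were high, are in the mean of the other 5. In all, 57 genes were higher and 24 lower by at least 1. The leucine arrays were the only ones of strain DBY9497, so nutrient and strain cannot be told apart. Within days 1 and 2 the branched-chain list was at 1.17 ± 0.27 and 1.46 ± 0.13 and the iron regulon at 1.34 ± 0.44 and 1.55 ± 0.19, of which the day 1 values did not pass (adjusted p = 0.071 and 0.14), and with day as a random block 79 genes were set apart.

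**Figure D4:**
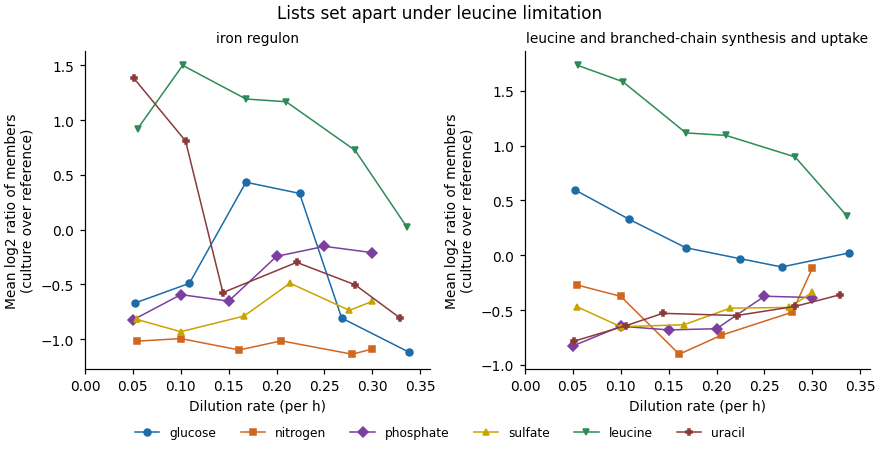
Mean log2 ratio of culture over reference (vertical axis) of the iron regulon and of the branched-chain list against dilution rate in per h, with 1 point per array and lines joining the 6 arrays of a nutrient. At the mean rate the leucine arrays were higher than the mean of the other 5 nutrients by 1.46 for iron genes and 1.55 for the branched-chain list.

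Under uracil limitation the changes were smaller. URA1, the dihydroorotate dehydrogenase of pyrimidine synthesis, was higher by 3.25 ± 0.10, YRO2 by 2.32 ± 0.26, the riboflavin enzyme RIB4 by 2.18 ± 0.09, the polyamine exporter TPO2 by 1.83 ± 0.23, the cell wall protein SED1 by 1.71 ± 0.20 and the malate dehydrogenase MDH2 by 1.48 ± 0.14. The pyrimidine list was higher by 0.47 ± 0.05, with 7 of 15 members higher and 8 not called (8 higher and 1 lower adjusted over the list alone), including URA4 (1.31), FUR1 (0.78) and URA6 (0.53). The sulfate permease SUL1 (-2.37 ± 0.19), the peptide transporter PTR2 (-2.22 ± 0.16), URA3 (-1.92 ± 0.06) and PHM6 (-1.54 ± 0.11) were lower, of which PHM6 was at -0.38 without the phosphate arrays. In all, 20 genes were higher and 34 lower by at least 1. The uracil arrays were the only ones of DBY9492, so nutrient and strain cannot be told apart. The pyrimidine list was at 0.58 ± 0.06 within day 2 and 0.32 ± 0.22 within day 3, where it did not pass (adjusted p = 0.49), and with day as a random block 57 genes were set apart.

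**Figure D5:**
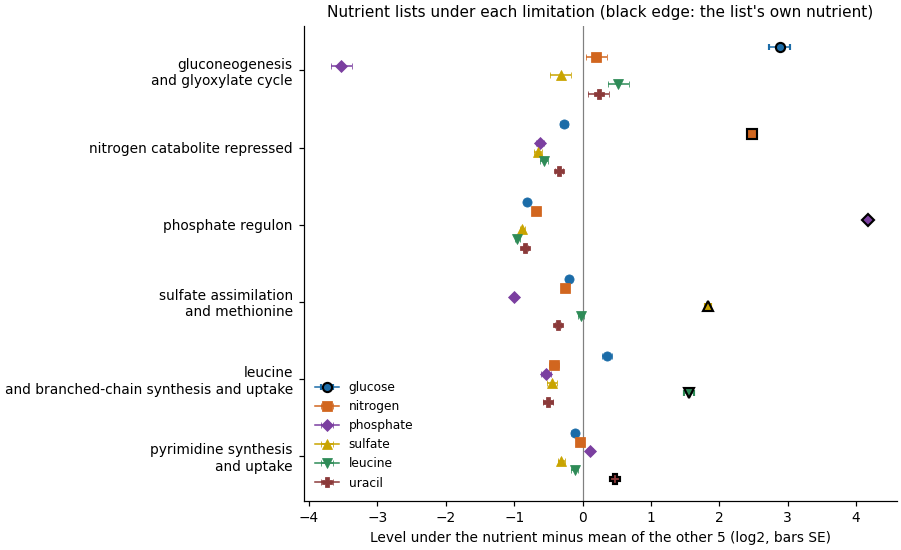
Level of 6 gene lists under each limiting nutrient minus the mean of the other 5 nutrients at the same rate (log2, horizontal axis, bars SE), with a black edge at the nutrient each list was chosen for. Each of the 6 lists shown is highest under its own nutrient, from 4.17 for the phosphate regulon to 0.47 for pyrimidine genes. The hexose transporter list, also chosen for glucose, is not shown. It was at -0.04 under glucose and highest under phosphate (0.33). The gluconeogenesis list is at -3.53 on the phosphate arrays, whose green channel differs.

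The leucine and uracil arrays limit strains that need the nutrient, and the contrast of both with the other 4 asks whether such limitations differ from natural ones. Iron genes were higher: FIT3 by 2.93 ± 0.42, FIT2 by 1.98 ± 0.23, the messenger RNA decay factor TIS11 by 1.95 ± 0.21 and the metal reductase FRE1 by 1.73 ± 0.18, with the flocculin FLO1 (1.92 ± 0.29), a member of a gene family, and the splicing factor SNP1 (1.83 ± 0.26). The iron list was higher by 1.13 ± 0.13, with 19 of 20 members higher. At the mean rate leucine limitation carried most of this, with 1.46 and 18 members higher, against 0.35 and 4 members for uracil alone, which did not pass (adjusted p = 0.077). On the slowest arrays the iron list mean was 1.38 under uracil and 0.92 under leucine, against -1.02 to -0.67 under the other nutrients. From 0.144 per h upward the uracil means were -0.81 to -0.30. The uracil arrays at 0.051 and 0.105 per h were extracted on day 3 and the other 4 on day 2. Rate and extraction day therefore cannot be told apart for this break. The iron list slope, which rests on it under uracil, was -1.75 ± 0.39 under uracil and -0.89 ± 0.39 under leucine. The auxotroph slope difference of the list was -1.43 ± 0.35 (limma, adjusted p = 0.0065). PUT4 (-2.06 ± 0.13), PHM6 (-2.01 ± 0.08), EEB1 (-1.80 ± 0.22), HPF1 (-1.62 ± 0.23), SUL1 (-1.57 ± 0.15) and PHO11 (-1.58 ± 0.06) were lower, of which PHO11 was at 0.06 and PHM6 at -0.60 without the phosphate arrays. The nitrogen arrays, on which PUT4 was high, are in the mean of the other 4. Levels differed by at least 1 for 75 genes, 42 higher and 33 lower. Slopes differed for 596 genes, 257 higher and 339 lower. ALD6 (2.00 ± 0.30), EEB1 (1.85 ± 0.58), the glutamate synthase GLT1 (1.80 ± 0.22), ATO3 (1.68 ± 0.34), the aconitase ACO1 (1.63 ± 0.23) and ENO1 (1.60 ± 0.44), a copy of ENO2, had higher slopes in the auxotrophs. FIT3 (-3.79 ± 1.10), TIS11 (-2.82 ± 0.56), TMA10 (-2.56 ± 0.59), FLO1 (-2.54 ± 0.76), SNP1 (-2.54 ± 0.68) and FET3 (-2.38 ± 0.57) had lower ones. Other pairs of nutrients set against the remaining 4 gave up to 162 genes for levels and up to 1345 for slopes. The slope calls of EEB1, ENO1, FIT3, FLO1 and SNP1 ended with median centring (1.79, 1.56, -3.20, -2.36 and -2.10) and without the phosphate arrays (1.42, 1.45, -3.43, -2.45 and -2.40). With median centring 223 genes differed, and with day as a fixed term 388 did, where ENO1 (1.27), FIT3 (-3.96) and FLO1 (-2.73) did not pass. With day as a random block the counts were 76 for levels and 600 for slopes.

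LEU2 and URA3 were examined because the leucine and uracil arrays came from other strains. URA3 had a mean log2 ratio of -2.08 ± 0.22 (SD, n = 6) on the uracil arrays and between -0.29 and -0.05 on those of the other nutrients, yet it was well above background on 6 of 6 uracil arrays. LEU2 had 0.28 ± 1.15 (SD, n = 6) on the leucine arrays, from 1.52 down to -1.54, and it too was well above background on all 6. On the phosphate arrays every LEU2 spot carried an outlier mark, and with those spots kept its mean was -0.48 ± 0.22 (SD, n = 6).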

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

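The tests of the phosphate regulon's green share, of the slowest arrays of every nutrient and of other pairs of nutrients were chosen only after the result was seen.

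Of the genes set apart on the phosphate arrays, the reference channel carried a median share of 0.732 of the ratio contrast, and 311 genes differed in that channel, a signal outside the ratio itself. The values are those expected from another reference RNA or another scan batch in green, which may account for most of those level calls. In green, gene lists moved both ways, gluconeogenesis by 3.14 ± 0.03 and glycolysis by -1.09 ± 0.02. Green intensities of the other arrays, extracted on several days, correlated at Spearman 0.993 to 0.999. These values argue against a scan batch as the sole cause. For the phosphate regulon the share was -0.0602, which argues against the green channel as the explanation for this list. A culture difference stays open for the 160 genes set apart in the red channel, of which 94 were called the same way in the ratio. In red the stress response was higher by 0.67 ± 0.10, with 33 of 42 members higher and 1 lower. Its ratio was at -0.47 ± 0.09, so the ratio can hide a difference that red shows. Extraction day cannot be told apart from phosphate limitation, since all 6 arrays share day 5.

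The iron regulon was higher under leucine limitation by 1.46. The lowest contrast within a day was 1.335, the contrast without the phosphate arrays was 1.481, and 18 members were higher, which argue against extraction day, the phosphate reference and a few members as the whole cause. The strain and the limitation itself stay open and untested, since DBY9497 was used for leucine alone.

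More genes had a rate slope under nitrogen limitation (3136) than under any other nutrient. Without the slowest nitrogen array, the one with most outlier spots, the count was 1874, below 2482 for uracil, but leaving out a nutrient's own slowest array lowers its count in each of the 6, so that array's part cannot be told apart from the shorter range of rates. Without the slowest array of every nutrient nitrogen still had 2316 genes and no other more than 1436, which argues against the slowest arrays alone. Extraction day stays open: the slower nitrogen arrays were extracted on days 3 and 4 and the 2 fastest on day 2, and with day as a fixed term nitrogen had 2007 genes against 1977 for phosphate. A response specific to nitrogen stays open and untested.

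Single arrays lay far from the other 5 of their nutrient in 7 of 54 groups tested, where chance gives about 1 in 20. They were a leucine array with a median red intensity of 310.9, and a nitrogen array with 90.26% and a sulfate array with 84.88% of spots well above background. The others were a nitrogen array with 350 and a sulfate array with 140 outlier spots, a uracil array with a pyrimidine list mean of -0.04125, and a phosphate array with a prediction error of 0.102 per h.

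Slopes differed between nutrients, by the F test, for cytosolic (6.652) and mitochondrial (4.346) ribosomal proteins, ribosome biogenesis (2.854), RNA polymerases (3.351), transfer RNA synthetases (3.374) and the stress response (3.607). They differed for trehalose (3.944), oxidative stress (5.756), glycolysis (5.321), gluconeogenesis (5.439), pentose phosphate (3.199), the tricarboxylic acid cycle (3.842), the respiratory chain (3.711), peroxisomes (19.4), sulfate (29.5), phosphate (7.876), nitrogen (7.917), hexose (5.766), branched-chain (11.78) and other amino acid (7.622) genes. They also differed for ergosterol (3.3), iron (4.481), zinc (6.484), G1/S (3.454), mating type a (6.938) and alpha (4.744) and haploid (8.291) genes. Among genes F was 50.11 for ZPS1, 44.19 for PXA1, 38.32 for FAT3, 35.43 for SOL3, 32 for ACS1, 31 for CIT3, 30.74 for OAC1, 28.39 for MTM1, 29.23 for LEU1 and 26.07 for DCI1. With extraction day as a fixed term the differences no longer passed for ribosome biogenesis (1.905), RNA polymerases (2.369), transfer RNA synthetases (2.013), trehalose (3.034), pentose phosphate (2.534), the respiratory chain (1.755) and ergosterol (2.807), nor with day as a random block for ribosome biogenesis (2.837). Slopes of the auxotrophs differed by 1.997 for ALD6, 1.855 for EEB1, 1.8 for GLT1, 1.678 for ATO3, 1.633 for ACO1, 1.605 for ENO1, -3.786 for FIT3, -2.818 for TIS11, -2.557 for TMA10, -2.537 for FLO1, -2.535 for SNP1 and -2.376 for FET3.

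In 100 regroupings each, the real one included, at most 2 reached the real value of any result below. Permuting rates removes every rate effect. It argues against chance for the presence of rate slopes but does not ask whether slopes are equal between nutrients. Permuting nutrients breaks up every nutrient, so for levels it asks only whether the arrays of a nutrient are more alike than random sets. With rates permuted within nutrients, the real and highest other counts were 1724 and 101 for rising genes, 2104 and 104 for falling genes and 1850 and 1094 for slope differences. They were 1772 and 147 for glucose, 3136 and 2028 for nitrogen, 1857 and 133 for phosphate, 1532 and 85 for sulfate, 1677 and 88 for leucine and 2429 and 736 for uracil slopes, and 18.6% and 3.85% for the variance with rate. Each of these was reached by 1 regrouping, the real one. With nutrients permuted within rates they were 170 and 36 for glucose, 108 and 135 for nitrogen, 420 and 126 for phosphate, 113 and 133 for sulfate, 81 and 35 for leucine and 54 and 102 for uracil levels. Nitrogen, sulfate and uracil levels were reached by 2 of the 100, and for these the other had 4 phosphate arrays under the label, a structure of the samples that follows extraction day. With day as a random block these 3 counts were 108, 113 and 57. For the auxotrophs the highest others were 560 against 596 slopes and 77 against 75 levels, but these regroupings break up the nutrients and so do not ask whether auxotrophy sets 2 nutrients apart. With nutrients kept whole, 4 of the 15 pairs of nutrients gave as many slopes, up to 1345, and 11 as many levels, up to 162, the real pair included, and 15 pairs are too few for a share under 0.05.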

How the results depend on the processing

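The red channel alone, the phosphate arrays left out (with or without day as a fixed term) and outlier spots kept were chosen after seeing the data. Of counts and matched lists over all alternatives 1526 stayed the same, 37 moved and 1 reversed. Same means within 1.5 times for counts and within 1 SD for values without a test. For tests it means the same side of the threshold and the same direction, with direction ignored where neither fit passed. Of list values 4601 stayed the same, 206 lost and 72 gained a call and 3 reversed. Of named genes 17188 stayed the same, 99 lost and 8 gained a call and 10 reversed. Most of those that stayed the same, 1069, 2969 and 10908 in this order, came from leaving out single arrays. The cause was not tested for any change below unless stated. With median centring 996 genes and 12 lists differed in slope, 223 genes differed for the auxotrophs, 8 lists fell, nutrient pairs correlated at 0.7057, and slopes reversed for TEF2 (0.9754), NDE1 (0.1978), COX5A (0.02231), PRE6 (0.04593), HTB1 (0.4156), HTA1 (0.9099), the respiratory chain (0.1746), the proteasome (0.09478) and fatty acid synthesis (0.2494). With the Feature Extraction log ratio 284 genes were set apart for glucose, 193 for nitrogen, 850 for phosphate, 179 for sulfate, 127 for leucine, 116 for uracil and 125 for auxotroph levels. With the log2 of the rate 3258 genes differed in slope and 987 for the auxotrophs. With day as a fixed term nitrogen had 2007, sulfate 410 and uracil 1462 slopes and the auxotrophs 388. A minimum of 1 on the log2 scale left 99 rising and 238 falling genes, by its construction. By camera 10 lists fell with a preset correlation, and 0 rose and 0 fell with an estimated one, against 3 and 3 at an unadjusted p under 0.05. The median of the hexose members under glucose was 0.1016. In the red channel alone 160 genes were set apart for phosphate, ICL1 was at 0.04291 and PCK1 at 0.001241 there, and TEF2 had a slope of 0.2664. Without the phosphate arrays 1183 genes and 13 lists differed in slope and PHO11 was at 0.05977 for auxotroph levels, with fewer arrays.

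Leaving out each array in turn gave 1118 (nitrogen at 0.05 per h) to 2877 (nitrogen at 0.3 per h) slope differences, 332 (leucine at 0.05 per h) to 820 for the auxotrophs, and slope counts of 896 to 2021 for glucose, 1874 to 3283 for nitrogen, 916 to 2078 for phosphate, 279 to 1798 for sulfate, 401 to 1940 for leucine and 604 to 2639 for uracil, each lowest without the nutrient's own array at 0.05 per h. Without their array at 0.3 per h glucose had 1095 and phosphate 1054. The value table was not run apart, since it is within 0.0005 log2 of the Feature Extraction ratio, nor was the mean of probes, since each gene has 1. Levels could not be fitted with day as a fixed term while phosphate arrays were in. Signal over background limited the 328 dim genes left out.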

Other observations

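The test of a slower reference was chosen only after the result was seen.

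The green channel of the phosphate arrays may hold RNA of a glucose-limited culture slower than the one in green on the other arrays. Across genes, its contrast with the other arrays had a Pearson r of -0.5422 with the rate slope of the red channel under glucose, which the hypothesis needs, against -0.37 to -0.46 for the slopes of the other 5 nutrients. Genes are not independent replicates, the pattern was found and tested on the same data, and another reference of another kind stays open. A contrast between arrays cannot tell which reference departs from the labelled 0.25 per h. Against the reference of the glucose arrays, the gluconeogenesis mean was still 0.84 at 0.268 per h and 0.20 at 0.338 per h.

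The JLP1 signal was higher on the sulfate arrays by 8.07 in red and by 2.88 in green. The labels name the same reference for these arrays, and green intensities outside the phosphate arrays correlated at Spearman 0.993 to 0.999. The green value therefore need not show more JLP1 RNA in the reference, and its cause was not tested. It lowers the ratio contrast of 5.08.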
